A study of Zea mays with 4 samples.

How the data were processed

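Digital gene expression tag profiling was applied to maize ears, the female inflorescences, of an inbred line, with 1 library from each of 4 stages of ear development. Per the labels' protocols, messenger RNA was selected from 6 µg of total RNA on oligo(dT) beads and turned into cDNA on the beads, and the cDNA was cut with NlaIII at CATG, so that only the 3' fragments were kept. Per the same protocols, MmeI then cut 17 bases past each CATG, an adaptor was joined to that end, and the tags were amplified over 15 PCR cycles and read on an Illumina instrument with reads of 35 bp. Every tag is therefore a 21-base sequence that begins with CATG and comes from the 3' part of a transcript.

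Per the file headers, each deposited file lists distinct tags with a copy number, which is the raw count of that tag in the library, and a TPM value. The count column held whole numbers from 1 upward, and the TPM column deposited by the authors equalled the count scaled to a library of 1000000 tags within 0.005. The tests used the counts alone, and the TPM values below, which are tags in 1000000 tags of the library, were recomputed from them. Base calling, adaptor trimming, tag filters and any aligner are not given in the sources used here. Tags seen once were present in every library.

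A reference of transcripts or a genome was not used here. The gene table at hand, for the assembly Zm-B73-REFERENCE-NAM-5.0, pairs names and identifiers of 49888 genes without sequence, so no tag could be tied to a gene. Tags are therefore reported by sequence, and the 29 gene lists fixed before the data were examined have no value. The design of each test, the alternatives and the rule for named tags were also fixed before the data were examined, except where another choice is said to have been made later.

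Libraries were compared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Between 2 libraries, a tag passed when its TPM values differed at least 2-fold and a two-sided exact conditional binomial test of its counts gave a Benjamini-Hochberg adjusted p of at most 0.001, over tags with at least 10 copies in at least 1 of the 2 libraries. With 1 library per stage there is no replicate check. This read-level test compares the libraries, not the stages. The test and the intervals of folds and of library shares cover counting error only. They may understate it, because PCR copies without molecular identifiers are not independent molecules. Bootstrap intervals, and the bound on a share of tag pairs, cover the spread among tags or pairs of these libraries. None covers differences between libraries of the same stage. For a fold, a count of 0 was set to a floor of 3 counts per library, and the fold is then given as a bound. The words at least mark such a fold. This bound rests on the floor and is not a 95% limit. The exact lower 95% limit by totals is smaller and is given beside it. Intervals of folds are exact conditional binomial intervals at 95%, and intervals of shares are Clopper-Pearson intervals at 95%, none of which reached further than 0.0485 percentage points from its share.

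A linear trend in stage order from 1 to 4 was tested with edgeR 4.0.16 under R 4.3.3, by the quasi-likelihood test with TMM scaling, over tags with at least 20 copies in total and at an adjusted p of at most 0.05. This fit has 2 residual degrees of freedom, and its spread is the deviation of the 4 libraries from a straight line. A tag counted as highest in a single library when it lay at least 4-fold above each of the other 3 and passed the read-level rule against each. Since no gene reference was used, the rule for named tags took, per comparison and direction, the 4 tags with the largest fold among those passing with at least 50 TPM in the higher library. From the trend and the single-library rule it took the 5 tags per direction or library with the highest mean level.

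Other settings fixed beforehand were TMM factors, size factors and a Wald test from DESeq2 1.42.0, other count minimums, tags seen once left out, thinning of all libraries to the smallest, an adjusted p of at most 0.05, assumed biological coefficients of variation of 0.2 and 0.4 in edgeR's exact test, and a trend without each library. After the data were seen, a further scaling was added because library ratios followed the last bases of the tag. Tags were sorted into 22 classes by their last 2 bases, or, for tags ending in 2 or more A, by the length of that A run up to 8. In each comparison the median log2 ratio of a class, over tags with at least 100 copies in total and with a pseudocount of 1, was taken as no change for its members. Bounds given within a class take its median as exact. For the trend within end classes, the class median of each library's deviation from the mean of the 4 libraries was used, with library totals in place of TMM. Runs with an assumed coefficient of variation also required a 2-fold difference, but at an adjusted p of at most 0.05. By totals they used edgeR's exact test, and within end classes its likelihood ratio test.

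The scripts were tested on simulated counts drawn at the level and depth of the real tags. For the read-level rule these counts held counting error only, without other differences between libraries. False calls near 0 without an end effect therefore follow from the setting and do not give the false calls in real libraries. Changed tags were drawn from tags more abundant than the rule's minimum requires, so recovery of rarer tags was not measured. With 100 tags changed 3-fold and 100 changed 8-fold, the read-level rule recovered 64% and 84% between the spikelet and growth point libraries, over 47009 tags tested, with 0 false calls. The same shares were 70% and 87% between the floret primordium and spikelet libraries over 45873 tags, 64% and 87% between the floret organ and floret primordium libraries over 41824 tags, and 66% and 91% between the floret organ and growth point libraries over 45378 tags, each with 0 false calls. When 1 constant effect per end class was imposed on all tags, scaling to totals gave 9160, 4727, 7058 and 11722 false calls in the same order. Scaling within end classes gave 0, 0, 0 and 1. The imposed effect used the same 22 classes as this scaling. The result therefore checks the scripts, and not whether the effect in the real libraries has that form. The trend test recovered 69% of 100 tags with a slope of 1 log2 unit per stage and 6% of 100 tags with a slope of 0.5, and called 2 of 59039 unchanged tags, at a simulated dispersion of 0.05.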

Results

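Tag profiles were taken from maize ears at 4 stages, 1 library each, so that the course of transcript levels through ear development could be compared. At growth point elongation the inflorescence meristem at the tip of the ear lengthens. During spikelet differentiation the spikelet meristems are laid down along its sides. They then form floret primordia, and in the last stage collected the organs of the florets take shape. The growth point elongation library held 3931920 tags of 270298 distinct sequences, and the spikelet differentiation library 4066158 tags of 278664 sequences. The floret primordium library held 4054326 tags of 256999 sequences and the floret organ library 4055577 tags of 238767 sequences. Of the 602080 sequences, 80492 were seen in all 4 libraries and made up 91.6% of all tags. Between 52.3% and 56.0% of the distinct sequences of a library were seen once, but these held 3.30% to 3.75% of its tags. The 10 most abundant tags took 3.99% to 4.41% of a library. The depth sets a floor of 0.738 to 0.763 TPM, which is what 3 counts are worth.

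The libraries differed in the bases at which their tags end. Tags ending in T made up 24.4% of the growth point elongation library and 14.1% of the spikelet differentiation library, but 33.1% and 37.1% of the floret primordium and floret organ libraries. Tags ending in A made up 37.5%, 47.3%, 24.8% and 19.4% in stage order. Tags ending in TT went from 3.66% and 1.54% to 10.9% and 13.7%, and tags ending in 5 or more A from 9.55% and 12.0% to 2.64% and 0.621%. The base next to CATG differed far less, with T there in 34.2% to 36.6% of tags. The number of tags that passed in each comparison is therefore given also with scaling within end classes, which was added after the data were seen. Tags named in a comparison are those with the largest folds among passing tags with at least 50 TPM in the higher library.

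**Figure D1:**
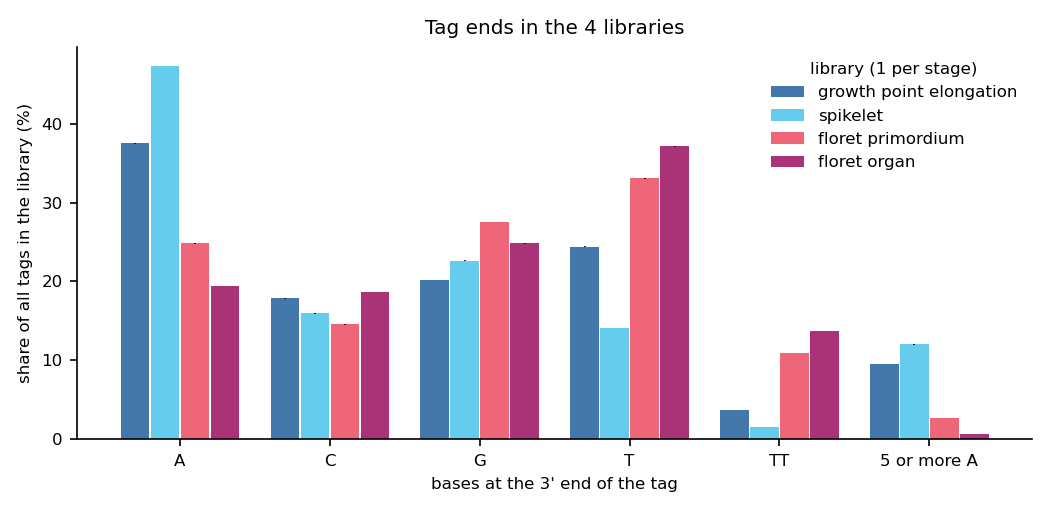
Share of all tags of each library, in percent, by the bases at the 3' end of the tag, 1 bar per library, with exact 95% binomial intervals that are narrower than the lines. TT ends took 1.54% of the spikelet differentiation library and 10.9% of the floret primordium library, while tags ending in 5 or more A took 12.0% and 2.64%.

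**Figure D2:**
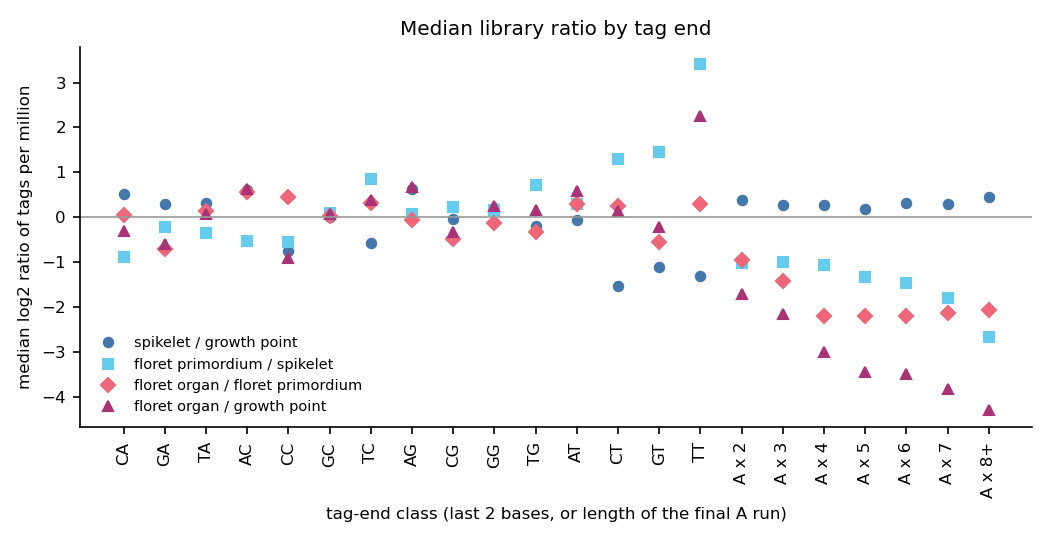
Median log2 ratio of TPM values in each tag-end class, over tags with at least 100 copies in total, 1 symbol per comparison of 2 libraries. The TT class stood at 3.41 between the floret primordium and spikelet differentiation libraries, and the class of 8 or more A at -4.29 between the floret organ and growth point elongation libraries.

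Tags of the same transcript could be compared where a tag contains a further CATG whose following bases begin 1 other tag. In 304 such pairs of neighbouring tags, the difference between the library ratios of both tags followed the difference between the medians of their end classes, with slopes of 1.01 (95% bootstrap interval 0.87 to 1.15), 0.868 (0.778 to 0.951) and 0.669 (0.427 to 0.905) in the 3 successive steps.

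**Figure D3:**
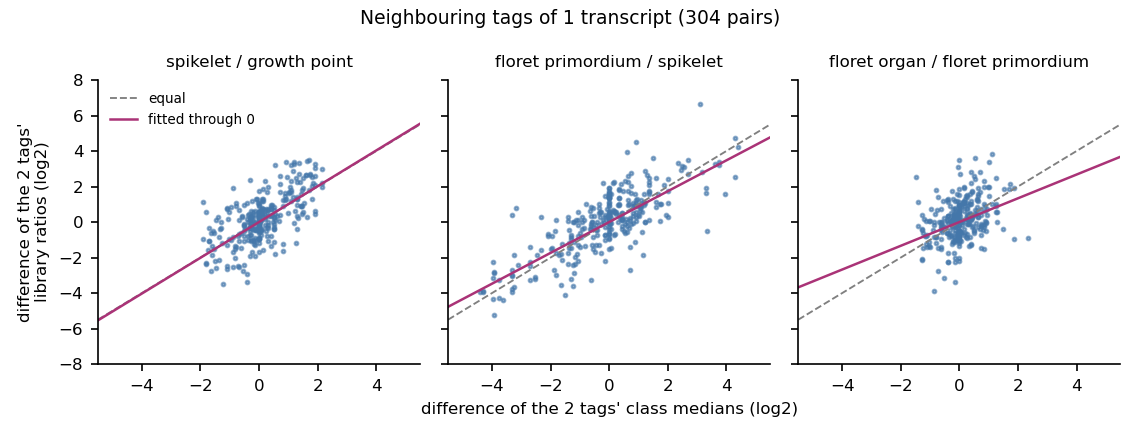
Difference of the log2 library ratios of 2 neighbouring tags of 1 transcript against the difference of the medians of their end classes, 1 point per pair, for the 3 successive steps. The dashed line marks equality and the solid line is fitted through 0, with slopes of 1.01, 0.868 and 0.669.

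From growth point elongation to spikelet differentiation, the 2 strongest rises among tags with at least 50 TPM were of tags nearly absent at the growth point. CATGGCATAGCCTACTATTGG was counted 1 time in the growth point library and 260 times in the spikelet library, 251-fold higher (95% interval 44.7 to 9968), and was at 0 in both floret libraries. CATGACAAAGTAAAACGTACA rose 153-fold (42.1 to 1271), from 2 to 317 copies, and stood at 176 and 15 copies in the floret primordium and floret organ libraries. CATGAACACCGAAAAAAACAC rose 15.2-fold (10.8 to 22.0), from 8.90 to 135 TPM. CATGAACCGCTTGTACGTGTA rose 14.9-fold (10.8 to 21.1), from 40 to 617 copies, and was back at 26 and 0 copies in the floret libraries.

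The 4 tags with the largest falls from at least 50 TPM stayed low in the floret libraries. CATGCTCTGTTTCTGTATCCT fell 95.8-fold (32.5 to 468), from 278 to 3 copies, with 0 and 3 copies in the floret libraries. CATGTTCTGTATTTTATGTCT fell 47.8-fold (20.2 to 149) and CATGTGGACTTGTGGCATTGT 47.6-fold (22.8 to 119), the latter from 322 to 7 copies and then to 2 and 0. CATGGAAGTATTAAAAAAACT fell 32.2-fold (15.4 to 81.1), from 55.4 to 1.72 TPM. The 4 falling tags end in CT or GT, classes whose medians stood at -1.53 and -1.10 in this comparison, and within their classes they were lower by 33.2-fold, 16.6-fold, 22.1-fold and 11.2-fold. The 4 rising tags remained 217-fold, 107-fold, 9.93-fold and 11.9-fold higher within theirs.

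Of 50132 tags tested between these libraries, 8463 passed, 3257 of them higher and 5206 lower in the spikelet differentiation library. Among tags with at least 50 TPM in the higher library, 735 were higher and 908 lower by totals, and 430 and 573 under both scalings. Scaling within end classes gave 5595 tags, 2288 higher and 3307 lower, and 4065 passed in the same direction under both scalings. With an assumed biological coefficient of variation of 0.4 and an adjusted p of at most 0.05, 90 tags passed edgeR's exact test by totals. Within end classes 119 passed its likelihood ratio test.

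Between spikelet and floret primordium differentiation, 2 tags appeared that were almost confined to the floret primordium library. CATGCTCTAGTATCGTCCTTG rose 639-fold (114 to 25273), from 1 copy to 637, and had 1 copy at growth point elongation and 0 at floret organ differentiation. Within its end class it was 390-fold higher. CATGCTAAAGTCCAAACAATC was counted 272 times in the floret primordium library and 0 times in the other 3. It was at least 90.9-fold higher than in the spikelet library by totals (lower 95% limit 73.5) and at least 50.1-fold within its end class. CATGGATTTCTATTCCTTGTT rose 79.9-fold (27.0 to 390), from 3 to 239 copies, and CATGTTCAGGCTGTAGTTATT 78.7-fold (30.4 to 291), from 4 to 314, and both stood higher again in the floret organ library, at 403 and 448 copies. Both end in TT, and within that class they were 7.54-fold and 7.43-fold higher.

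CATGACTATCAACGGTGTCGA, counted 463 times at growth point elongation and 222 times at spikelet differentiation, fell 221-fold (39.3 to 8782) to 1 copy in the floret primordium library and was at 0 in the floret organ library. CATGGCATAGCCTACTATTGG, which had risen in the step before, was at least 86.4-fold lower (lower 95% limit 69.8). The tags CATGCAGCTACAAAAAAAAAA and CATGCAGCTAAAAAAAAAAAA, which differ at 1 base, fell 33.4-fold (22.3 to 52.4) and 24.2-fold (16.6 to 36.7), from 198 and 167 to 5.92 and 6.91 TPM. They end in 8 or more A, a class with a median of -2.67 here, and within it they were 5.25-fold and 3.80-fold lower.

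In this comparison 12417 of 49787 tags passed, with 6614 higher and 5803 lower in the floret primordium library. TT ends were carried by 2794 of the higher tags, or 42.2%, against 8.03% of the tags tested, and ends of 2 or more A by 3894 of the lower tags, or 67.1%, against 22.5%. Scaling within end classes left 3066 tags, 1172 higher and 1894 lower, so that the share of higher tags went from 53.3% to 38.2%. When tags ending in 2 or more A were left out instead, the share of higher tags was 62.8%. Under both scalings 1899 tags passed in the same direction, 272 of those higher and 251 of those lower having at least 50 TPM, and 144 passed in opposite directions. With an assumed coefficient of variation of 0.4 and an adjusted p of at most 0.05, 2081 tags were higher and 855 lower by totals. These came from edgeR's exact test. Its likelihood ratio test within end classes gave 28 higher and 77 lower. By library totals this step had the most differing tags of the 3 successive steps, and within end classes it had the fewest.

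From floret primordium to floret organ differentiation, CATGTTTGATGGTTGAGAAGA went from 0 to 468 copies, at least 156-fold higher (lower 95% limit 126). It had 0 and 2 copies in the growth point and spikelet libraries. CATGAGAAAGCCAACTGTGAC rose from 4 to 240 copies (95% interval of the fold 23.1 to 222) and was at 0 in both earlier libraries. CATGTAAAGAAGCAGAGGAAC rose 19.2-fold (10.8 to 37.8) and CATGCCGAGAGAGCTCAAGAT 16.2-fold (9.46 to 30.1), to 57.0 and 56.0 TPM. Within their end classes the 4 tags were at least 255-fold, 40.3-fold, 12.9-fold and 13.3-fold higher, where the bound is for the tag with a count of 0.

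Among the falling tags, CATGTTAACTGAATTTTTAGA held 1850, 1464 and 1318 copies in the first 3 libraries and 10 in the floret organ library, 132-fold lower (71.5 to 276) than at floret primordium differentiation. CATGATGACCATCGTCGACGA, at 1, 180 and 371 copies before, was at 0, at least 124-fold lower (lower 95% limit 100). CATGCTCTAGTATCGTCCTTG and CATGCTAAAGTCCAAACAATC, the tags of the floret primordium library, were at 0, at least 212-fold and 90.7-fold lower (lower 95% limits 172 and 73.3). Within their end classes the 4 falling tags remained lower, by 80.5-fold for CATGTTAACTGAATTTTTAGA and by at least 75.6-fold, 170-fold and 113-fold for the 3 at 0, in the order given.

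Of 44093 tags tested here, 5240 passed, with 1582 higher and 3658 lower in the floret organ library. Ends of 2 or more A were carried by 42.7% of the lower tags against 12.4% of those tested. Scaling within end classes gave 3239 tags, 1685 higher and 1554 lower, and 2225 passed in the same direction under both scalings. The share of higher tags was 30.2% by totals, 52.0% within end classes, 41.4% with DESeq2 size factors and 40.1% with TMM factors. The DESeq2 and TMM factors move every log2 ratio of this comparison by 0.12 and 0.10. With an assumed biological coefficient of variation of 0.4 and an adjusted p of at most 0.05, 173 tags passed edgeR's exact test by totals. Within end classes 368 passed its likelihood ratio test.

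**Figure D4:**
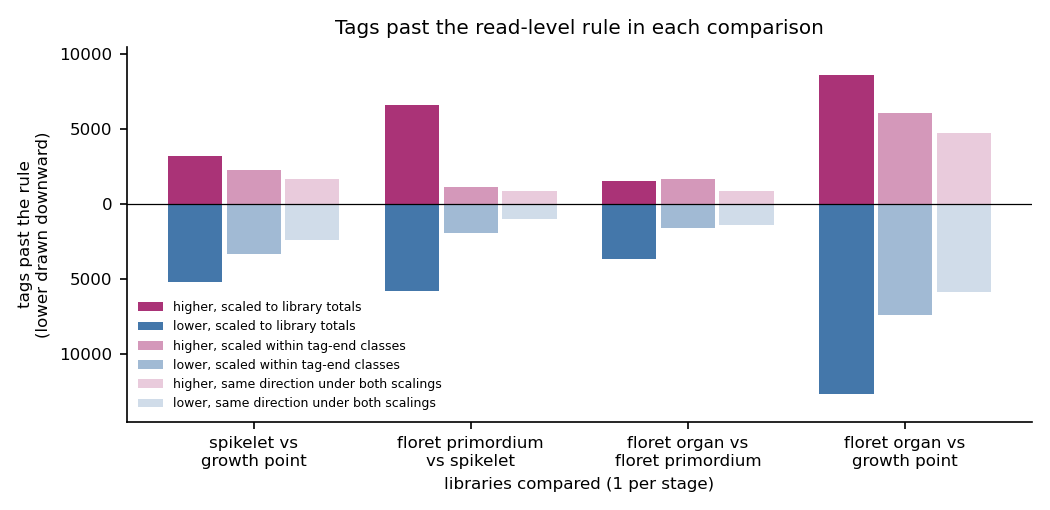
Numbers of tags past the read-level rule in each comparison of 2 libraries, higher tags drawn upward and lower tags downward, by library totals, within tag-end classes, and in the same direction under both. The step from spikelet to floret primordium differentiation went from 12417 tags to 3066, and the comparison of the floret organ with the growth point elongation library from 21291 to 13502.

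Over the whole course, from growth point elongation to floret organ differentiation, CATGTACATAGGTTGTCAATA fell from 2690 through 1269 and 136 to 3.95 TPM, 682-fold in all (420 to 1193). The median of its end class was 0.08, and within the class it was 722-fold lower. CATGCAGTTCTATTAAAAAAA fell from 915 copies to 1, a 944-fold fall (169 to 37317). CATGCAGCTACAAAAAAAAAA fell 620-fold (171 to 5129), from 1203 copies to 2, and CATGCTTTTGGTAAAAAAAAA 581-fold (104 to 22977), from 563 copies to 1. These last 3 end in runs of A, whose classes stood at -3.81 and -4.29, and within them they were lower by 67.1-fold, 31.7-fold and 29.6-fold.

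Among the 4 tags with the largest rises to at least 50 TPM, CATGATTTTTGTATATTCGAT was counted 1, 18, 75 and 308 times in stage order, 299-fold higher at the end (53.2 to 11832), and 199.6-fold within its class. CATGCCGGACTAGTTGCTTTT had 2, 0, 56 and 413 copies, 200.2-fold higher (55.1 to 1659) by totals and 41.8-fold higher within the TT class. CATGCCTAAGGACATCCAGCT had 12, 21, 337 and 1568 copies, 127-fold higher (72.3 to 246) and 115-fold within its class. CATGTTTGATGGTTGAGAAGA, at least 151-fold higher by totals (lower 95% limit 123) and at least 229.7-fold within its class, appeared in the last step.

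**Figure D5:**
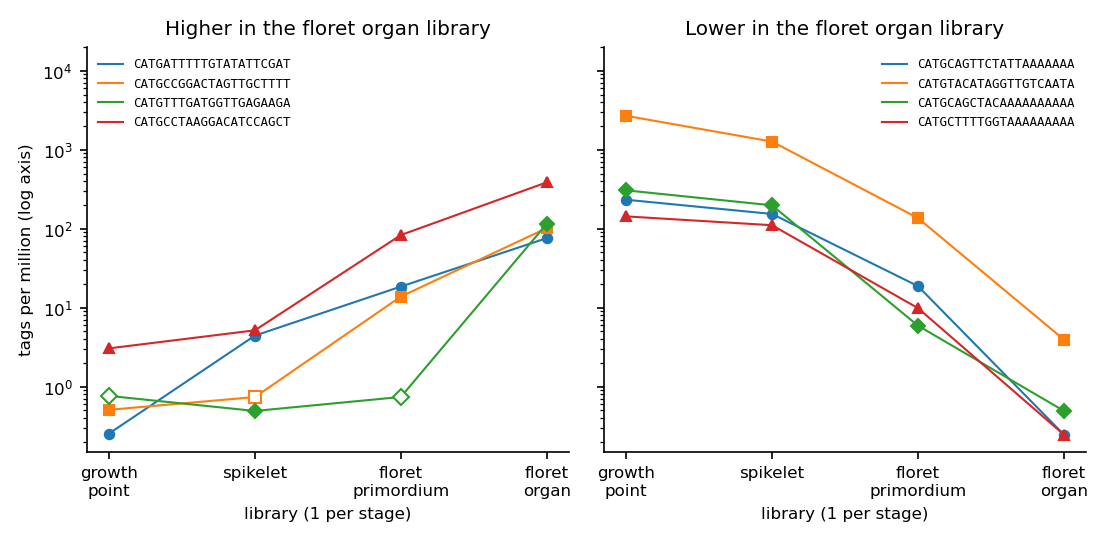
TPM values (log axis) of the 8 named tags of the comparison between the floret organ and growth point elongation libraries, 1 line per tag and 1 library per stage. Open symbols mark a count of 0, drawn at the level of 3 counts. CATGTACATAGGTTGTCAATA went from 2690 to 3.95 TPM, and CATGCCTAAGGACATCCAGCT from 3.05 to 387.

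Between the floret organ and growth point elongation libraries 21291 of 51696 tags passed, 8653 higher and 12638 lower. Scaling within end classes gave 13502 tags, 6104 higher and 7398 lower, and 10604 passed in the same direction under both, 4765 higher and 5839 lower. With an assumed biological coefficient of variation of 0.4 and an adjusted p of at most 0.05, 12907 passed edgeR's exact test by totals. Within end classes 6604 passed its likelihood ratio test. The median level of the 5839 lower tags went from 18.3 through 8.61 and 5.67 to 2.22 TPM, and 956 of them were at 0 in the floret organ library. That of the 4765 higher tags went from 4.58 through 8.12 and 16.5 to 24.7 TPM. The same read-level rule, under both scalings, was passed by 1631 of the lower tags in the step to spikelet differentiation, by 629 in the next and by 909 in the last. For the higher tags these numbers were 889, 484 and 667. Both groups were chosen by their end points, and 3050 of the lower and 2868 of the higher tags passed no single step, while 74 and 25 passed a step in the opposite direction.

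A linear trend over the 4 stages was called by edgeR for 365 of 59239 tags, 112 rising and 253 falling. Of the 365, 265 changed in the same direction at every step by TPM, and the others did not. With library totals in place of TMM edgeR called 60, and with tags seen once left out it called 0, where 13209 had an unadjusted p of at most 0.05, while the Wald test of DESeq2 called 6449 on all tags. CATGCCCAAGGACATCCAGCT had the highest level among the rising tags, with 83.4, 115, 761 and 2944 TPM, a slope of 1.83 log2 units per stage (edgeR adjusted p = 0.0484). CATGCAAAGAGAGTTGTGTTT rose from 39.7 to 1101 TPM and CATGTTCGACCTATTCAATTT from 8.14 to 349, with slopes of 1.77 and 2.09 that were 0.73 and 1.00 within end classes. Among the falling tags, CATGTACATAGGTTGTCAATA had a slope of -3.05, CATGTACATAATAATGAATAA went from 1166 to 2.47 TPM with a slope of -2.74, and CATGTATTTTAAAACTTATAA from 1741 to 16.8 with a slope of -2.07. CATGCAGCTACATATTTAAAA went from 979 to 1.97 TPM with a slope of -2.86. CATGGTGTTTAGCATTGATTT and CATGTTTTGCCCAAAAAAAAA were also called, at slopes of 1.77 and -1.95, but within end classes their slopes were 0.56 and -0.42 with edgeR adjusted p = 0.249 and 0.182. The lowest adjusted p was 0.0455, so that all calls lay close to the threshold. Within end classes, where library totals took the place of TMM, 5465 tags were called, 339 of them among the 365. With TMM scaling and no end classes, the count was 3 without the floret organ library and 390 without the floret primordium library. It was 4714 without the growth point elongation library and 10821 without the spikelet differentiation library.

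Tags highest in a single library numbered 1487, of which 956 belonged to the growth point elongation library. CATGTAGGTTTGTTCAATGTC stood there at 1375 TPM, 5.83-fold (5.44 to 6.25) above the nearest library but 3.90-fold within its end class, below the rule. CATGGAGCTACGACGCGATTC stood at 869, 6.64-fold (6.06 to 7.29) above the nearest library and 4.44-fold within its class. CATGTGCTACACGGTTACTTG was 6.15-fold (5.52 to 6.86) above the nearest library. CATGTGGTCCGCTCTACTGCT, at 1128 TPM, and CATGCCGAATAATGGATGTGT, at 862, were 4.06-fold and 5.46-fold above it but 1.41-fold and 2.54-fold within their end classes, also below the rule. The floret organ library had 281 such tags. CATGGAAACTATCCACTTAAT reached 374 TPM there, 9.31-fold (7.92 to 11.0) above the nearest library, CATGTATGGTATTGTGTTAGT 271, 6.67-fold (5.66 to 7.90) above it, and CATGCTTAAGTGCTTGATTTG 156, 10.9-fold (8.34 to 14.6) above it, and all 3 kept the call within end classes. CATGAGAGGATGTCGTCGTCT was highest by level, at 471 TPM and 4.08-fold (3.68 to 4.52) above the floret primordium library, but 3.45-fold within its end class, below the rule. CATGCCTAAGGACATCCAGCT, at 387 TPM, was 4.65-fold (4.13 to 5.25) above that library and 3.94-fold within its class, below the rule too.

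The spikelet differentiation library had 184 tags of its own, 38.6% of them ending in 2 or more A, and the floret primordium library 66, of which 24 ended in TT. In the spikelet library, CATGTTTAGTGTAGATCCGCA reached 314 TPM, 4.72-fold (4.14 to 5.40) above the nearest library but 2.56-fold within its end class, below the rule. CATGCATGCACCAACGGGGAG reached 113, 6.09-fold (4.76 to 7.88) above the nearest library. Its smallest fold within its class was 6.40, against the growth point elongation library. CATGTACTTTTACCGCACTAC and CATGTTCTATGATGTACTTTA were 5.37-fold and 4.40-fold above the nearest library but 3.70-fold and 3.51-fold within their classes, below the rule, and CATGAACCGCTTGTACGTGTA was 14.9-fold above it and 11.9-fold within its class. In the floret primordium library, CATGGGCGGTTGTAAAATCTG reached 463 TPM, 4.33-fold (3.90 to 4.81) above the nearest library. Its smallest fold within its end class was 3.38, against the spikelet library and below the rule. CATGGTCTCTGTTGGACAACT reached 65.1, 10.7-fold (7.02 to 16.9) above the nearest library, with a smallest fold of 5.37 within its class, against the spikelet library. CATGGTCATCGGGGGAACCTT and CATGGATCATCTCTCTATCTT were 5.33-fold and 8.82-fold above the floret organ library, the nearest by totals. Within the TT class their smallest folds were 1.75 and 2.25, against the spikelet library and below the rule. CATGCTCTAGTATCGTCCTTG was at least 212-fold above the floret organ library (lower 95% limit 172) and at least 170-fold within its class. Scaling within end classes gave 721, 123, 21 and 364 such tags in stage order, of which 516, 70, 20 and 160 were the same tags.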

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

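The scaling within end classes and the leaving out of tags ending in 2 or more A were chosen after seeing the data. TMM factors, DESeq2 size factors, both count minimums, thinning and tags seen once left out kept each of the 4 pairwise counts within 1.5 times. An adjusted p of at most 0.05 gave 15367, 20781 and 10294 tags in the 3 successive steps, because more tags pass a looser threshold. An assumed coefficient of variation of 0.2 also stayed within 1.5 times, but at that looser threshold. Its counts lay below the read-level counts at the same threshold in all 4 comparisons. All settings with an assumed coefficient of variation used that threshold, and within end classes another test. In the order reported, end classes gave 5595, 3066, 3239 and 13502 tags, a coefficient of variation of 0.4 gave 90, 2936, 173 and 12907, and both together 119, 105, 368 and 6604. With 0.2 and end classes the step to floret primordium gave 2457 and the next step 2953, and without tags ending in 2 or more A the former gave 8207. Trend calls numbered 60 with totals in place of TMM, 6449 with DESeq2's Wald test (12634 tags had no adjusted p), 3871 without the filter, 5465 within end classes, 1587 without tags ending in 2 or more A and 3 to 10821 with 1 library left out. They numbered 0 in edgeR when tags seen once were left out, where 13209 had an unadjusted p of at most 0.05, and the cause of these changes was not tested. Tags highest in a single library numbered 4054 at 2-fold, which admits more tags, and in total stayed within 1.5 times in all other settings. The 32 log2 ratios of named tags kept their direction and passed with TMM factors, without tags seen once and within end classes, moving by up to 0.16, 1.59 and 4.29. Not run were 17 settings that need a match of tags to genes, and no gene list was measured. No paired analysis was possible because each stage has 1 library. Without tags seen once, 105129 to 129045 distinct tags were left per library. Below the floor of 3 counts per library, depth does not allow a tag to be called absent.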

Other observations

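The tests on tag ends and on pairs of tags here were chosen after the dependence on the tag end had been seen, and those on positions, on library totals, on tags sharing the bases before an A run, on pairs within end classes and on tags differing at 1 base after their own values had been seen.

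Some transcripts carried 2 tags that overlapped, because a tag contained a further CATG whose following bases began exactly 1 other tag over at least 15 bases. There were 304 such pairs, against a mean of 6.90 when the overlapping bases were shuffled. Between the floret organ and growth point elongation libraries both tags passed under both scalings in 48 pairs, both higher in 16, both lower in 29 and in opposite directions in 3. The pair within CATGTCATGAATACAAACTGAGTTTG fell from 1821 to 36.7 and from 1885 to 135 TPM, 49.6-fold (42.1 to 58.7) and 14.0-fold (12.8 to 15.3). The pair within CATGCATGCTCTATTATAGCTAGTC fell 39.6-fold (23.4 to 73.0) and 14.4-fold (12.2 to 17.2). The pair within CATGCATGTTTTAAGTAGCATCCCA rose 4.66-fold (4.19 to 5.19) and 3.02-fold (2.74 to 3.32), and that within CATGCATGAAGTCCCCCCGTCGCTC 13.2-fold (10.5 to 16.8) and 48.8-fold (16.4 to 239). The pair within CATGCATGCACCAAGTGTTACTATA fell from 137 to 39.2 and from 322 to 136 TPM (95% intervals of the folds 2.93 to 4.21 and 2.14 to 2.63), and that within CATGCATGTATTATGCCATATGTAG rose 3.74-fold (2.95 to 4.77) and 5.20-fold (3.89 to 7.07). Within end classes the folds of these pairs in the order named were 32.6 and 15.6, 43.5 and 18.8, 3.11 and 3.71, 10.1 and 37.5, 5.43 and 2.51, and for the last 3.27 at the downstream tag and less at the upstream tag. The pairs named are the 3 per direction with the highest mean level, a rule set after the data were seen.

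The most abundant tags had courses of their own. CATGTTTTGCCAGCGCGTAAT led the growth point elongation library at 12052 TPM and stood at 6589, 3181 and 631 in the later libraries. CATGGTGGTGACGGGTGACGG led the spikelet differentiation library at 7234 TPM, with 3999 before and 5668 and 3841 after. CATGGGATAACATCATAGGAT led both floret libraries, at 3201, 4430, 6705 and 10895 TPM in stage order. CATGATAATGCTATGAGAACT ranked next in the floret organ library, at 566, 360, 2639 and 4328.

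Between the floret primordium and spikelet differentiation libraries the last 2 bases of a tag accounted for 66.8% of the variance of the log2 ratios over 23475 tags, and 32.9%, 32.9% and 36.7% in the other comparisons in the order reported, where without tags ending in 2 or more A these were 33.1%, 15.3% and 17.7%. Different transcripts would shift all positions of a tag, but in tags not ending in 2 or more A no pair of positions that leaves out the last 2 bases accounted for more than 1.11%, against 61.4% at the last pair and 14.5% at the pair sharing 1 base with it (with tags ending in 2 or more A kept, up to 12.3% in the comparison of the floret libraries and 9.23% in this one), and library size is argued against by totals of these libraries that lie within 0.292% of each other. Tags of the same transcript that end differently offer a direct test: the difference of their library ratios followed the difference of their class medians with a slope of 0.877 (95% bootstrap interval 0.798 to 0.955) over the 3 successive steps, in line with a tag-end effect of preparation or sequencing. A candidate explanation is the joining of the adaptor to the overhang that MmeI leaves at the end of the tag, but the step at which the effect arose was not tested.

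Tags ending in 5 or more A were lower in the floret organ than in the growth point elongation library, with a median log2 ratio of -3.57 over 1696 of them that share the bases before the A run with another tag. If their transcripts had fallen, those other tags, where they come from the same transcripts, would have been lower as well. Their median log2 ratio was 0.51 (95% bootstrap interval 0.42 to 0.63), and 0.21 (0.11 to 0.27) within end classes. The shared stretch could be as short as 12 bases with CATG included, and accidental matches to other transcripts were not measured. A fall of the transcripts is therefore not excluded. A move of polyadenylation sites away from CATG sites also remains possible. It was tested on 12 pairs in which an A run lies inside the transcript, where the slope was 0.363 with an interval from -0.29 to 1.04, and 10 of these runs hold exactly 2 A, so it cannot be told apart from a loss of A-ended tags.

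More tags differed between the floret organ and growth point elongation libraries than between any successive libraries, 13502 within end classes. The tag end as the whole cause is argued against by neighbouring tags of a transcript, whose ratios within end classes went together across 117 pairs (Pearson's r = 0.783, 95% bootstrap interval 0.635 to 0.876). Plants of another genotype in 1 of these libraries would make tags that differ at 1 base replace each other. Pairs were taken where both tags had at least 200 copies in their highest library, and pairs with very unequal highest counts were left out. Between these libraries 0% of 651 such pairs moved at least 4-fold in opposite directions (upper 95% bound 0.565%), against 2.75% of random pairs. Another genotype in the spikelet or floret primordium library was not tested. With 1 library per stage, the stage cannot be told apart from any other difference between single libraries, such as a batch or day. Of the 12 orders of the libraries, too few for a share under 0.05, the real order gave 365 trend calls and the highest other 1813, from the order with the growth point and spikelet libraries exchanged, while within end classes these were 5465 and 7.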
